A study of Homo sapiens with 4 samples.

How the data were processed

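The series holds 4 one-colour gene expression arrays of 2 human oesophageal squamous cell carcinoma (ESCC) lines, TE2 and TE15. Each line was transfected with a siRNA against CD63 (siCD63) or with a negative control duplex (siCont), 30 pmol per well, and total RNA was taken after 48 h, per the labels' protocols. From each RNA, 100 ng was amplified and labelled with Cy3 and hybridised to an Agilent SurePrint human gene expression array. There was 1 array per cell line and treatment, so n = 1 in each of the 4 groups, and all 4 arrays lay on 1 slide read in 1 scan.

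The deposited values are fluorescence intensities on a linear scale, written by Agilent Feature Extraction 10.7.1.1 per the file headers and the submitters' processing notes. Per the file headers, the scanner software had subtracted background and detrended each array, replaced the dimmest spots by a small positive surrogate, and had not scaled the arrays to one another. The same deposited files give an error-model estimate for each intensity and flags for control spots, saturation, outlier spots and signal well above background. Each array held 62976 spots, of which 60901 were not controls. No spot was saturated. Well above background were 25406 of 58201 probes for TE2 siCont (43.7%), 24408 for TE2 siCD63 (41.9%), 26022 for TE15 siCont (44.7%) and 24892 for TE15 siCD63 (42.8%). The median processed signal of the negative control spots was 5.29, 6.30, 5.24 and 6.02 in the same order. Probes printed on 10 spots had a median SD of 0.0517, 0.0488, 0.0494 and 0.0484 log2 units within an array. The number of arrays limits the precision of every comparison.

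Control spots and spots with an outlier flag were left out, spots of one probe were averaged on the log2 scale, and the 75th percentile of each array was subtracted from its log2 processed signal. Because most probes of each array were not above background, the percentile was taken over the 21308 probes above background on all 4 arrays, and the percentile over all probes was an alternative chosen after the data were seen. Probes were named by the RefSeq accession in the files, matched without version to the symbols of the GRCh38.p14 annotation; 31100 of 58201 probes (53.4%) received 1 gene symbol, none several, and 27101 stayed unnamed here. The design of the array was built on hg19 per the file headers, so no coordinates are given. Of 22435 named genes, 6754 had 2 or more probes, and each was taken at the probe with the highest mean over the 4 arrays.

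Within a line, the log2 difference siCD63 minus siCont was taken for genes above background on 1 or both arrays, and a signal not above background was raised to the lowest signal above background of its array, so that such differences are bounds. With 1 array against 1 there is no test within a line. The error-model SE of a difference, with a median of 0.204 log2 units in both lines, covers array error only and leaves out the spread between cultures. For a gene detected in only 1 of 2 groups, "at least N-fold" sets the brighter signal against the higher of the dim signal and the lowest signal above background.

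Over both lines, 14954 genes above background on at least 2 of 4 arrays were fitted with limma 3.58.1 in R 4.3.3, with cell line and treatment as terms, empirical Bayes moderation (residual degrees of freedom 1, prior 2.35) and Benjamini-Hochberg adjustment at 0.05. The lines are the only repeats of the treatment, so this test measures how alike they responded. The cell line term of the same fit compared TE15 with TE2. A model with an interaction leaves 0 residual degrees of freedom, so the difference of response between the lines has no test. Agreement was tested with Fisher's exact test across genes and described by correlations across genes, which are not independent replicates. A total of 41 gene lists was fixed before the data were examined, as were the tests, the naming rule and all alternatives except that percentile and list medians over members above background on at least 1 array of the line. List shifts were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 41 lists. The measured members of a list are those in the fit over both lines, so some are above background in the other line only and enter the medians and counts of a line at their measured signal. In each line the median of a list is given with its percentile among 10000 random lists of the same size matched on mean signal, as a description without p.

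The rule for naming took CD63 first. Over both lines it took the 10 highest and 10 lowest genes by the smaller of the 2 absolute differences among genes above background on all arrays, and in each line the 6 highest and 6 lowest. For TE15 against TE2 it took the 10 largest differences each way among genes past the test and past 2-fold under both siRNAs. From each list it took up to 4 members with the largest absolute mean difference, and among genes detected on 1 array of a line the 3 highest bounds each way. Unnamed, uncharacterised, open-reading-frame and Y-linked symbols, XIST and TSIX were left out.

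The steps were tested on simulated data drawn from the real gene means and the fitted variance prior in 5 rounds, over 14954 genes except within a line. For siCD63 against siCont over both lines, 1 of 250 genes planted at 2-fold, 151 of 250 at 4-fold, 212 of 250 at 8-fold and 234 of 250 at 16-fold was called, against 44 of 73770 unchanged genes. For TE15 against TE2, 622 of 1000 planted genes were called. Camera called 5 of 5 shifted lists and 0 of 100 others with the preset correlation, and 0 of 5 shifted lists with the estimated one. A list that fails with the estimated correlation is therefore no evidence against its shift. Every member of the shifted lists was moved 2-fold. Smaller shifts were not simulated, such as the mean differences of the basal squamous (0.34), squamous differentiation (0.31) and heat shock (0.27) lists below. The simulated genes varied independently, so these counts do not cover lists whose members vary together. Within a line, simulated over 22435 genes, 500 of 500 genes planted at 4-fold were found past 2-fold. These were planted only in genes above background on both TE2 arrays and clear of the detection floor. The simulated noise was that of the arrays alone, so the count does not cover dim genes or the spread between cultures.

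Alternatives were normexp background correction with an offset of 50, quantile normalization, array-median scaling, no filter on dim probes, a filter on all arrays compared, the mean over the probes of a gene, thresholds of 1.5-fold and 3-fold, limma-trend, robust moderation, no cell line term, an adjusted p of 0.1 and the estimated correlation. The planned normexp step called for mean signals, and the median signal and median background were used in their place. Its offset is added to every signal on the linear scale, which by itself shrinks the log2 differences of dim genes. Without a filter, measured signals were used with no floor. Intervals of medians in the closing tests come from 10000 bootstrap draws over genes. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the files and drew the plots, and the R package data.table (version 1.17.8) held the values.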

Results

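Gene expression was measured in TE2 and TE15, both established lines of human oesophageal squamous cell carcinoma, 48 h after transfection with siCD63 or siCont. CD63 is a tetraspanin of late endosomes, lysosomes and extracellular vesicles. Each of the 4 groups (TE2 siCont, TE2 siCD63, TE15 siCont, TE15 siCD63) was measured on 1 array, so differences within a line have no replicate check. Signals are log2 values relative to the 75th percentile of their array, and differences are siCD63 minus siCont unless another order is named.

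CD63, measured by 1 probe designed on NM_001257389, was lower with siCD63 in both lines. In TE2 its signal was 5.18 with siCont and 1.47 with siCD63, a difference of −3.72 with an error-model SE of 0.204, or 13.2-fold lower. In TE15 it was 5.27 with siCont and 0.93 with siCD63, a difference of −4.34 with an error-model SE of 0.204, or 20.3-fold lower. CD63 had the lowest difference of any gene above background on all 4 arrays in each line. Over both lines the mean difference was −4.03 (SE 0.21, limma adjusted p = 0.291).

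**Figure D1:**
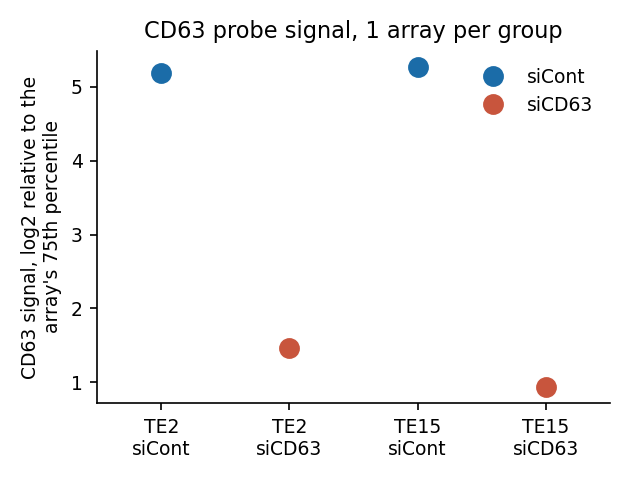
CD63 probe signal on each array, in log2 units relative to the 75th percentile of the array on the vertical axis, with 1 point per array and cell line and siRNA on the horizontal axis. The siCont arrays lie at 5.18 (TE2) and 5.27 (TE15) and the siCD63 arrays at 1.47 and 0.93.

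The TE2 comparison asks which genes differ after CD63 knockdown in that line. The highest differences in TE2 were those of TRIM31, an E3 ubiquitin ligase (3.09), the squamous cell carcinoma antigens SERPINB3 (2.66) and SERPINB4 (2.65), the alcohol dehydrogenase ADH1C (2.63), complement component C3 (2.52) and the kelch-domain gene KLHDC7B (2.24). The lowest after CD63 were those of the interleukin-6 family cytokine IL11 (−3.61), the type II keratin KRT80 (−3.29), the cytokine IL24 (−2.89), the LIM-domain cofactor FHL2 (−2.66) and the secreted precursor VGF (−2.42). In TE15 the same differences were 0.52 for TRIM31, 0.07 for SERPINB3, 0.01 for SERPINB4, 0.03 for ADH1C, −0.24 for C3, −0.75 for IL11, −1.07 for KRT80, 0.22 for IL24 and −0.58 for VGF. A second C3 probe gave 2.32 in TE2 and a second FHL2 probe −2.53. SERPINB3 and SERPINB4 are near-identical paralogs whose probes may share transcripts.

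Of 14507 genes above background on at least 1 TE2 array, 379 (2.61%) were at least 2-fold higher with siCD63 and 393 (2.71%) at least 2-fold lower. The SD of the log2 difference over the 13617 genes above background on both arrays was 0.44, and the middle 95% of them lay between −0.96 and 0.90. Among genes detected on 1 TE2 array, the highest bounds with siCD63 were at least 7.18-fold for HOXA-AS2, 6.36-fold for OR8H1 and 5.81-fold for CMAHP, and with siCont at least 6.90-fold for TM6SF2, 5.92-fold for GNG13 and 5.61-fold for MIR7-3HG. The probe for 18S ribosomal RNA (RNA18SN5) differed by 2.12 in TE2 and by 0.27 in TE15. With normexp background correction the TE2 counts were 123 higher and 159 lower, and TRIM31 differed by 2.1, C3 by 1.92, KLHDC7B by 1.58, IL24 by −1.97 and VGF by −1.7.

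In TE15, the highest differences belonged to interferon response and interferon genes. They were the chemokine CCL5 (5.36, 41.0-fold higher), IFI44L (4.68), the antiviral enzyme RSAD2 (4.61), the type III interferon IFNL2 (3.90), IFI6 (3.73) and the RNA-binding antiviral gene IFIT1 (3.31). In TE2 the measured differences were 0.00 for CCL5, −0.44 for IFI6 and −0.29 for IFIT1, while IFI44L, RSAD2 and IFNL2 were not well above background on either TE2 array. The lowest after CD63 were the forkhead genes FOXS1 (−2.80) and FOXJ1 (−2.21), the latter a regulator of motile cilia, TMEM121 (−2.20), the cytosolic branched-chain aminotransferase BCAT1 (−2.20) and MOSPD3 (−2.18). In TE2, FOXJ1 differed by 0.03 and TMEM121 by −0.36, and FOXS1 was not well above background. With normexp background correction CCL5 differed by 4.04, RSAD2 by 3.8, IFNL2 by 2.31, FOXS1 by −1.63, FOXJ1 by −1.32 and TMEM121 by −1.18 in TE15. A second BCAT1 probe gave 0.21 in TE15, and a second MOSPD3 probe gave −1.97.

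Of 14697 genes above background on at least 1 TE15 array, 213 (1.45%) were at least 2-fold higher with siCD63 and 324 (2.20%) at least 2-fold lower. The SD of the log2 difference over 13892 genes was 0.39, and the middle 95% lay between −0.89 and 0.69. Among genes detected on 1 TE15 array, the highest bounds with siCD63 were at least 7.45-fold for the type III interferon IFNL1, 7.17-fold for LINC02883 and 7.06-fold for ZNF682, and with siCont at least 6.47-fold for the kinase MAP3K12, 5.12-fold for LINC02182 and 3.93-fold for TUBA3FP. With normexp background correction the TE15 counts were 108 higher and 94 lower, so that higher genes made up 53.5% of them and not 39.7%; with genes above background on both arrays alone, 123 were higher.

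Over both lines, the lowest shared differences after CD63 were those of GSDME, a pore-forming gasdermin (−2.35 in TE2 and −2.12 in TE15), CIAO2A, a factor of cytosolic iron-sulphur protein assembly (−2.06 and −2.08), TMEM117 (−1.88 and −1.98), DRAM1, a p53-induced lysosomal membrane protein (−1.88 and −1.97), and FHL2 (−2.66 and −1.76). They were followed by PEX19, the import receptor of peroxisomal membrane proteins (−1.73 and −1.96), MOSPD3 (−1.69 and −2.18), BCAT1 (−1.68 and −2.20) and the endocytic adaptor FCHSD2 (−1.62 and −1.74). The highest shared differences were those of 4 guide RNAs of pseudouridylation, SCARNA13 (1.73 and 1.56), SNORA51 (1.71 and 1.56), SCARNA1 (1.5 and 1.53) and SNORA48 (1.71 and 1.45), and of KLHDC7B (2.24 and 1.37). They were followed by TGS1, which trimethylates the caps of small nuclear and nucleolar RNA (1.39 and 1.32), the decapping cofactor DCP1A (1.26 and 1.26), the transcription factor TCFL5 (1.43 and 1.25), the integrin subunit ITGB8 (1.24 and 1.35) and the RNA-binding gene RBM38 (1.23 and 1.26). Other probes differed for BCAT1 (−0.09 in TE2 and 0.21 in TE15) and FCHSD2 (0.08 and −0.73, and −0.07 and −1.62), and went the same way for DCP1A, FHL2, KLHDC7B and MOSPD3. ITGB8 (−6.54) and SCARNA1 (−6.08) were dim in TE2 with siCont, where the detection floor was −7.15.

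The 2 lines shared more genes past 2-fold than independent lists would. Among 13374 genes compared in both, 90 were at least 2-fold lower in both lines against 5.51 expected (Fisher's exact test across genes, two-sided p = 6.23e-88), and 28 were at least 2-fold higher in both against 2.43 expected (p = 3.36e-22). In opposite directions, 6 genes were higher in TE2 and lower in TE15 against 4.69 expected, and 3 were lower in TE2 and higher in TE15 against 2.86 expected. Over the 12695 genes above background on all 4 arrays, the differences of the lines correlated across genes with Pearson's r = 0.457 and Spearman's rho = 0.436, with r = 0.453 without CD63, and 65.2% of genes had the same sign. Of these genes 82, CD63 included, were at least 2-fold lower in both lines and 24 at least 2-fold higher.

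**Figure D2:**
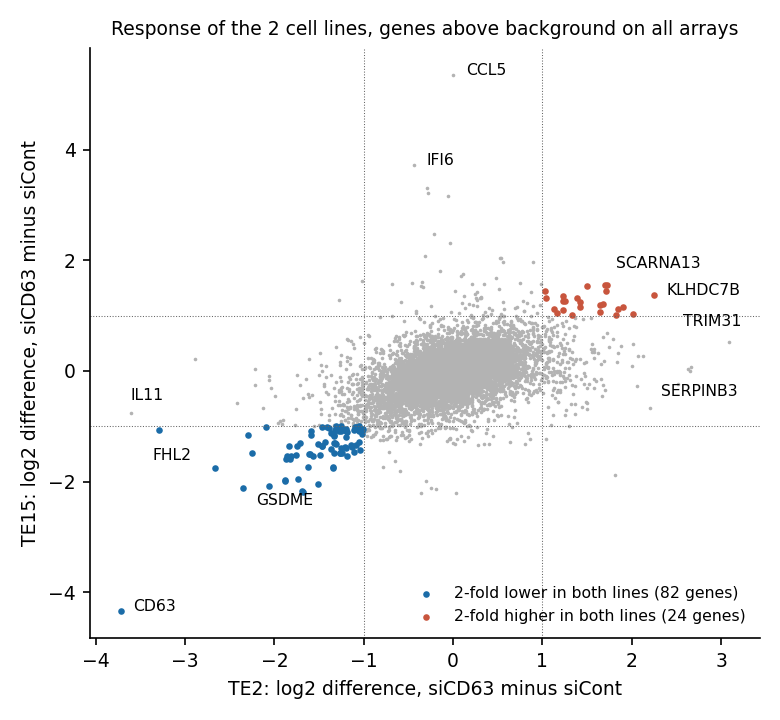
Log2 difference siCD63 minus siCont in TE2 (horizontal axis) and in TE15 (vertical axis), 1 point per gene above background on all 4 arrays, with dotted lines at 2-fold. The 82 genes at least 2-fold lower in both lines are blue and the 24 at least 2-fold higher are red, with CD63 at −3.72 and −4.34.

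No gene passed the limma test over both lines: 0 of 14954 genes were called, with a smallest adjusted p of 0.291, which all 19 named genes above and CD63 had. At an unadjusted p under 0.05 stood 1944 genes, 714 higher and 1230 lower, where 748 are expected with no effect. With normexp background correction 71 genes were called higher and 153 lower, and with limma-trend 26 and 70. CD63 and the named genes were among those called with normexp, except ITGB8, and with limma-trend, except ITGB8 and SCARNA1. The mean difference of SCARNA1 was 0.81 with normexp against 1.52 as reported.

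Among the gene lists, 4 of 41 passed camera with the preset correlation. The interferon-stimulated genes (33 measured) had a median of 0.03 in TE2 and 1.57 in TE15 (adjusted p = 6.84e-06), with 0 members at least 2-fold higher in TE2 and 25 in TE15, where all 33 were above 0. The p belongs to the mean difference over both lines and is no test of the rise in TE15 alone. Members of this list had an estimated correlation of 0.879, against the preset 0.01. The estimate rests on the 1 residual degree of freedom, which is the difference of response between the lines. It thus restates the rise in TE15 without TE2 and measures no spread over replicates. With an estimated correlation neither this list (adjusted p = 0.919) nor any other of the 41 passed (smallest adjusted p = 0.919). That setting also called 0 of 5 shifted lists in the simulation, so it cannot decide for or against a list. IFI6 differed by −0.44 in TE2 and 3.73 in TE15, HERC5, an ISG15 ligase, by −0.06 and 3.16, IFIT1 by −0.29 and 3.31, and OASL by −0.28 and 3.22. The list medians stood at percentile 71.8 of matched random lists in TE2 and, after rounding, 100 in TE15. In TE2, 7 of the 33 were above background on neither array, and the 26 others had a median of −0.06, with 0 at least 2-fold higher. Without a filter on dim probes the interferon-stimulated list had an adjusted p of 0.0694, the highest of the settings with a preset correlation, whose lowest was 2.62e-09. The leukocyte marker genes (11 measured) had a median of −0.09 in TE2 and −0.34 in TE15 (adjusted p = 0.197).

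**Figure D3:**
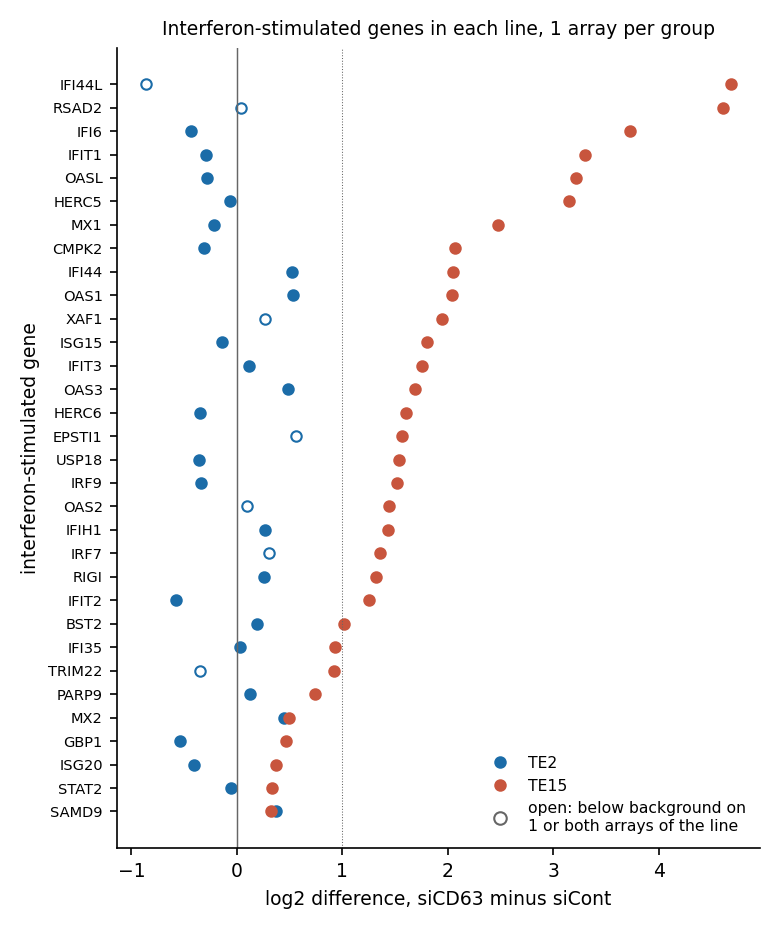
Log2 difference siCD63 minus siCont (horizontal axis) of 32 of the 33 measured interferon-stimulated genes (vertical axis), TE2 in blue and TE15 in red, 1 array per group. Open points were below background on 1 or both arrays of the line; over all 33 genes the median was 1.57 in TE15 and 0.03 in TE2.

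Both squamous lineage lists had medians above 0 in each line. The basal squamous keratinocyte genes (20 measured) had medians of 0.32 in TE2 and 0.31 in TE15, with 17 members above 0 in both lines and 0 below 0 in both (adjusted p = 0.000596; 0.919 with an estimated correlation). Members were the squamous lineage factors SOX2 (1.62 in TE2 and 0.33 in TE15) and TP63 (0.75 and 0.52), the hemidesmosome integrin ITGB4 (0.93 and 0.33) and KRT15 (0.95 and 0.22). The squamous differentiation genes (32 measured) had medians of 0.30 and 0.21, with 17 above 0 in both lines and 2 below 0 in both (adjusted p = 0.0273; 0.919 with an estimated correlation). Their largest values lay in TE2, where SERPINB3 differed by 2.66, SERPINB4 by 2.65, LCN2, a siderophore-binding secreted protein, by 2.02 and KRT6A by 1.54, against 0.07, 0.01, 0.48 and 0.41 in TE15. LCN2 (−6.47) and KRT6A (−6.86) were dim in TE2 with siCont, where the detection floor was −7.15. The call for this list was lost with quantile normalization (adjusted p = 0.078), with genes above background on all arrays (0.332) and with no filter on dim probes (0.299), and over all settings with a preset correlation its adjusted p lay between 0.0214 and 0.332. Of the 32 squamous differentiation genes 10 were above background on neither TE2 array, and the 22 others had a TE2 median of 0.05. The median of all 32 in TE2 was 0.02 with quantile normalization and 0.09 with normexp background correction, and in TE15 it was 0.09 with genes above background on all arrays. For the basal squamous genes these settings gave between 0.000355 and 0.0694, the latter with no filter on dim probes. In TE2 these shifts stood beside the difference of 2.12 in the 18S ribosomal RNA probe RNA18SN5.

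Heat shock genes (15 measured) had medians of 0.25 in TE2 and 0.28 in TE15, with 13 above 0 in both lines and 1 below 0 in both (adjusted p = 0.00356; 0.919 with an estimated correlation). With a preset correlation the other settings gave adjusted p between 0.00294 and 0.117, the latter with no filter on dim probes. The small heat shock gene HSPB1 differed by 0.29 in TE2 and 0.51 in TE15, the chaperone HSPA1A by 0.78 and 0.14, and HSPB8 by 1.5 and −0.31. HSPB8 was dim in TE2 with siCont (−6.70). SERPINH1, a collagen chaperone, was the member below 0 in both (−0.72 and −0.70). The 18S ribosomal RNA probe RNA18SN5 differed by 2.12 on the same TE2 arrays.

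Adjusted over the list alone, 7 list members passed, and over all genes tested 0 did. They were TSPAN17 among the tetraspanins (−1.19 in TE2 and −1.11 in TE15), the prolyl hydroxylases P4HA2 (−1.21 and −1.37) and EGLN1 (0.92 and 0.87) among the hypoxia genes, the enolase ENO2 among the glycolysis genes (−1.59 and −1.16), ITGB8 among the integrins and laminins (1.24 and 1.35), and COL1A1 (−0.71 and −0.67) and DPT (0.63 and 0.86, on 3 of 4 arrays) among the fibroblast markers. Their adjusted p over the list (limma, Benjamini-Hochberg) lay between 0.0188 (COL1A1 and DPT) and 0.0468 (EGLN1). Each list was adjusted on its own and not over the 41 lists, so some passes may come from the number of lists. The fibroblast list had only 4 measured members.

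None of the other 37 lists passed, and their smallest adjusted p was 0.0619. Among the lists on the compartment of CD63, the other tetraspanins (17 measured) had medians of 0.23 in TE2 and −0.07 in TE15 (adjusted p = 0.523), with CD82 at 0.90 and −0.11. Extracellular vesicle and ESCRT genes (23 measured) had medians of 0.00 and −0.03 (0.759), with the late endosomal GTPase RAB7A at 0.91 and 0.63, VPS37A at −0.84 and −0.55 and VPS4B at −0.43 and −0.47. Lysosomal genes (24 measured) had medians of 0.02 and −0.21 (0.447), with the sialidase NEU1 at −0.72 and −0.50, SCARB2 at −0.60 and −0.35, the cation channel MCOLN1 at −0.58 and −0.32 and GUSB at −0.29 and −0.59. Autophagy genes (18 measured) had medians of 0.15 and −0.14 (0.686), with the autophagy receptor OPTN at 1.31 and 0.23 and GABARAPL1 at 0.78 and −0.30.

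Inflammatory, antigen presentation and stress lists gave these values. The NF-kB and cytokine genes (22 measured) had medians of 0.31 in TE2 and 0.22 in TE15 (adjusted p = 0.0619), with the chemokine CXCL3 at 1.16 and 0.71, IL1A at 1.07 and 0.54, BIRC3 at 0.83 and 0.53 and IL6 at −1.92 and −0.96. Antigen presentation genes (16 measured) had medians of −0.10 and −0.01 (0.686). Unfolded protein response genes (19 measured) had medians of 0.13 and −0.07 (0.759), with the endoplasmic reticulum chaperone HSPA5 at −1.17 and −0.84 and XBP1 at 0.36 and 0.57. ATF4 and amino acid response genes (22 measured) had medians of −0.14 and 0.38 (0.286), with the cystathionine lyase CTH at 0.88 and 1.44, CHAC1 at 0.30 and 1.32 (0.02 and 1.39 at a second probe), MTHFD2 at 0.43 and 1.1 and the cystine transporter subunit SLC7A11 at 0.64 and 0.75. NRF2 targets (22 measured) had medians of 0.32 and −0.01 (0.162), with ferritin light chain FTL at 0.58 and 0.58, AKR1B10 at 1.20 and −0.34 and HMOX1 at −0.43 and −0.42. Genes of the small RNA pathway (16 measured) had medians of 0.07 and 0.03 (0.686), with AGO1 at −0.59 and −0.44 (−0.48 and −0.02 at a second probe).

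The lists of growth and survival held no gene called over all genes. G1/S and DNA replication genes (30 measured) had medians of 0.03 in TE2 and 0.04 in TE15 (adjusted p = 0.686), with the replication factor GINS1 at −0.87 and −1.14 and cyclin gene CCNE1 at 0.53 and 0.47. G2/M and mitosis genes (31 measured) had medians of 0.11 and −0.02 (0.686), with the kinase TTK at −0.46 and −0.57 and MKI67 at 0.60 and 0.24 (0.54 and −0.04, and 0.78 and 0.02, at other probes). The p53 targets (26 measured) had medians of 0.03 and 0.03 (0.828), with the p53 ubiquitin ligase MDM2 at −1.11 and −0.64 (−2.12 and −1.77 at a second probe), the death receptor TNFRSF10B at −0.62 and −0.62 and TP53INP1 at 1.16 and −0.39. TP53INP1 was dim in TE2 with siCont (−6.25). Cyclins, CDK inhibitors and RB genes of G1 (15 measured) had medians of 0.19 and 0.05 (0.455), with CDKN2D at −0.43 and −0.75. Apoptosis effectors (24 measured) had medians of 0.10 and 0.14 (0.180), with the death ligand TNFSF10 at 1.79 and 0.58 and BCL2L11 at 0.64 and 0.54, while other BCL2L11 probes gave −0.60 and −0.47, and 0.14 and 0.71. Apoptosis inhibitors (12 measured) had medians of −0.19 and −0.05 (0.718), with XIAP at −0.43 and −0.45 (−0.21 and −0.13 at a second probe).

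Signalling lists were as follows. EGFR/MAPK genes (28 measured) had medians of −0.16 in TE2 and 0.10 in TE15 (adjusted p = 0.686), with ETV5 at −1.11 and −0.49 and PHLDA1 at −0.92 and −0.46. PI3K/AKT/mTOR and FOXO genes (28 measured) had medians of 0.29 and −0.09 (0.686), with the receptor IGF1R at −0.69 and −0.70 and FOXO3 at 0.71 and 0.65. TGF-beta targets (20 measured) had medians of −0.29 and −0.17 (0.113), with TGFBR2 at −1.18 and −0.51, ID3 at −0.61 and −0.51 and BAMBI at 0.15 and 0.92. YAP/TAZ targets (19 measured) had medians of −0.31 and 0.27 (0.589), with WWC1 at −1.17 and −0.92, AJUBA at 0.52 and 0.97 and CCN1 at −1.20 and 0.03. Wnt genes (14 measured) had medians of −0.01 and 0.06 (0.523), with the ubiquitin ligase RNF43 at 1.03 and 0.67. Notch genes (15 measured) had medians of 0.00 and −0.03 (0.804), with HEYL at −0.73 and −0.68 and HEY1 at −0.41 and −0.77.

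Among adhesion and lineage lists, mesenchymal genes (21 measured) had medians of −0.17 in TE2 and −0.22 in TE15 (adjusted p = 0.388), with the repressor SNAI1 at −0.78 and −0.59, COL5A1 at −0.85 and −0.47 and the receptor kinase AXL at −0.59 and −0.22. Epithelial junction genes (22 measured) had medians of −0.01 and 0.08 (0.523), with CTNND1 at 0.71 and 0.36 and MARVELD2 at 0.47 and 0.52. Integrins and laminins (20 measured) had medians of −0.17 and −0.01 (0.523), with LAMC1 at −0.72 and −0.36. Metalloproteinase and plasminogen genes (19 measured) had medians of −0.11 and −0.06 (0.523), with MMP28 at 1.54 and 0.96, MMP9 at −1.16 and −0.55 and MMP1 at −1.61 and 0.22. Columnar epithelium genes (14 measured) had medians of 0.16 and 0.07 (0.686), with AGR2 at 1.33 and 0.22. Stem cell markers (18 measured) had medians of 0.06 and 0.24 (0.702), with the polycomb gene BMI1 at −0.85 and −0.71 and SOX9 at 0.13 and 1.14. Fibroblast markers (4 measured) had medians of 0.17 and 0.38 (0.664) and endothelial markers (2 measured) of 0.36 and −0.37 (0.998).

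Of the metabolic and reference lists, cholesterol and fatty acid synthesis genes (28 measured) had medians of 0.14 in TE2 and −0.22 in TE15 (adjusted p = 0.420), with the desaturase FADS1 at −0.65 and −1.63 and HMGCS1 at −0.69 and −0.99. Hypoxia genes (24 measured) had medians of −0.10 and −0.03 (0.523), with EGLN3 at −0.73 and −1.09. Glycolysis genes (17 measured) had medians of 0.08 and −0.07 (0.794), with PFKM at −0.85 and −0.40. Oxidative phosphorylation genes (25 measured) had medians of 0.08 and 0.10 (0.489), with NDUFV2 at −0.53 and −0.58. Ribosomal protein genes (28 measured) had medians of 0.02 and 0.07 (0.523) and housekeeping genes (17 measured) of 0.11 and 0.03 (0.523), with YWHAZ at −0.40 and −0.53. Under another background correction, scaling, filter or probe choice the median changed sign in TE2 for the extracellular vesicle, lysosomal, interferon-stimulated, ribosomal protein, epithelial junction, metalloproteinase, Wnt, Notch, fibroblast, leukocyte and endothelial lists. It did so in TE15 for the extracellular vesicle, antigen presentation, G2/M, hypoxia, integrin, metalloproteinase, Notch, NRF2, housekeeping and endothelial lists, so these medians carry no direction. With genes above background on neither array of the line left out, the TE2 median was −0.25 for the mesenchymal, −0.20 for the antigen presentation and −0.35 for the leukocyte genes, and the TE15 median −0.50 for the mesenchymal genes, −0.16 for the integrins and laminins and 0.13 for the YAP/TAZ targets. Over the settings with a preset correlation, the mesenchymal median lay between −0.32 and −0.01 in TE2 and between −0.25 and −0.02 in TE15. Over both lines the mean and the median of the members differed in sign for the extracellular vesicle genes (−0.01 and 0.02), the unfolded protein response genes (−0.01 and 0.04) and the Notch genes (0.02 and −0.01).

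TE15 had more RNA of epidermal keratins and TE2 more of vimentin, whichever siRNA they had received. Higher in TE15 were the keratins KRT5 (at least 2950-fold), KRT6B (at least 522-fold) and KRT6A (1590-fold), the epidermal calcium-binding gene CALML5 (1890-fold), the alarmin subunit S100A8 (at least 561-fold), the acute-phase genes SAA1 (at least 1830-fold) and SAA2 (at least 529-fold), the lipolysis inhibitor G0S2 (at least 950-fold), carbonic anhydrase CA9 (at least 683-fold) and the sialyltransferase ST6GALNAC1 (at least 490-fold). Higher in TE2 were the mesenchymal filament VIM (at least 2600-fold), the imprinted gene PEG10 (at least 1070-fold), EPDR1 (at least 941-fold), osteopontin SPP1 (at least 807-fold), the endodermal factor FOXA2 (at least 584-fold), RUNX3 (at least 577-fold), SGCE (at least 500-fold), PRSS21 (at least 416-fold), the ubiquitin hydrolase UCHL1 (1530-fold) and LDOC1 (at least 298-fold). Their limma adjusted p lay between 0.000724 and 0.0015, and "at least" marks genes not well above background in the dimmer line.

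Of 14954 genes tested, 4562 were higher and 4582 lower in TE15 (limma, Benjamini-Hochberg 0.05), 61.1% in all, and 2851 and 2227 of them were also at least 2-fold apart under both siRNAs. KRT6A and KRT6B, and SAA1 and SAA2, are close paralogs whose probes may share transcripts. The median difference over tested genes was −0.03, against −0.23 when the percentile was taken over all probes and −0.14 with array-median scaling. Of the genes called, 49.9% were higher in TE15 as reported, 40.2% with the percentile over all probes and 44.6% with array-median scaling. By list, 12 of 41 passed camera with the preset correlation and 0 with an estimated one (smallest adjusted p = 0.892). The estimated correlation again rests on 1 residual degree of freedom and cannot decide. Higher in TE15 were squamous differentiation genes (median 4.77, adjusted p = 3.72e-07, 28 of 32 members called higher), antigen presentation genes (1.97, 5.08e-05), interferon-stimulated genes (2.63, 0.000135; median 1.89 with siCont and 3.06 with siCD63), basal squamous genes (1.93, 0.000135), NF-kB genes (1.07, 0.0158), hypoxia genes (1.0, 0.0158), epithelial junction genes (0.77, 0.022) and metalloproteinase genes (1.12, 0.0371). Lower in TE15 were NRF2 targets (−1.05, 0.000475), G1/S genes (−0.89, 0.000714), oxidative phosphorylation genes (−0.54, 0.0207) and ribosomal protein genes (−0.27, 0.0387).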

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

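The count over unnamed probes was chosen after the results were seen, and no difference of response between the lines was tested, because 1 array per group leaves no residual degrees of freedom for it. The YAP/TAZ target genes had a median of −0.31 in TE2 and 0.27 in TE15, in opposite directions. The TE15 median was smaller, 0.08, with quantile normalization, 0.14 with normexp background correction and 0.13 with genes above background on all arrays. Among genes above background on all 4 arrays, 4 were past 2-fold in opposite directions. INHBA, which encodes an activin subunit, differed by −1.28 in TE2 and 1.28 in TE15, and IFITM1, an interferon-induced membrane protein, by −1.02 and 1.62. CFAP65-AS1 differed by 1.82 in TE2 and −1.88 in TE15, and RIMBP3 by 1.04 and −1.23. CFAP65-AS1 was dim in TE2 with siCont (−6.59, detection floor −7.15) and in TE15 with siCD63 (−6.44, floor −6.84). Over all genes compared, the counts in opposite directions were 6 and 3, against 4.69 and 2.86 for independent lists. Of 4503 probes above background on all arrays that received no gene symbol, 13 were at least 2-fold lower in both lines and 6 at least 2-fold higher, against 0.44 and 0.482 for independent lists, and the differences of the lines correlated across these probes with r = 0.253.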

How the results depend on the processing

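The 75th percentile over all probes was tried only after the data were seen, as were the list medians over members above background on at least 1 array of the line, and all other alternatives were planned. The percentile over all probes moved no count of genes past 1.5 times the reported one. Counts and calls that moved are given here, and where no cause is named the cause was not tested. With normexp background correction 123 genes were higher and 159 lower in TE2, 108 and 94 in TE15, 16 and 39 in both lines against 0.571 and 0.924 expected, and limma called 71 higher and 153 lower over both lines. With no filter on dim probes and no floor under dim signals, 960 were higher and 904 lower in TE2, 739 and 844 in TE15, and 92 and 166 in both lines against 31.6 and 34 expected, r across genes was 0.178, and 1 gene list passed, the TGF-beta targets (adjusted p = 0.032, the lowest of settings that reached up to 0.332). With genes above background on all arrays compared, 123 were higher in TE15, fewer genes being compared. At 1.5-fold, 1106 were higher and 1275 lower in TE2, 682 and 1144 in TE15, and 161 and 403 in both. At 3-fold, 88 and 79 differed in TE2, 63 and 63 in TE15, and 0 and 15 in both. With limma-trend 26 genes were called higher and 70 lower over both lines, and with an estimated correlation 0 gene lists passed. The estimated correlation also called 0 of 5 shifted lists in the simulation, so that loss decides nothing. The other 91 values of counts, correlations and calls stayed within their bounds, and none of the genes named for the largest differences over both lines or within a line reversed its direction. Some gene list medians changed sign, as named in the results. List members, host genes and genes that differ between the lines were not rerun one by one. CD63 lay between −3.72 and −3.61 in TE2 and between −4.46 and −4.31 in TE15 over all settings. For BCAT1 in TE15 the mean over its probes gave −0.99. No gene passed limma with the filter on all arrays (smallest adjusted p = 0.0989), with an adjusted p of 0.1, with robust moderation or with no cell line term. No array could be left out, since each group holds 1. The fit over both lines pairs the arrays by cell line, and without that term 87 genes stood at an unadjusted p under 0.05, against 1944 with it. Within a line, 1 array per group allows no pairing. Signal over background limits genes near the detection floor, where differences are bounds.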

Other observations

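In this part, the tests of leukocyte markers, of chance overlap, of other probes of the shared lower genes and of short RNA recovery, and all gene classes, were chosen after the results were seen. The host genes tested are those of SCARNA13, SNORA51, SCARNA1 and SNORA48, which were picked by rank from these same data. Among gene classes not fixed in advance, the H/ACA and Cajal body RNA genes (109 above background on all arrays), most of which guide RNA modification, had medians of 0.36 in TE2 and 0.35 in TE15, and 17 and 11 of them were at least 2-fold higher. The probe of another RNA without a poly(A) tail, 18S ribosomal RNA (RNA18SN5), differed by 2.12 and 0.27 on the same arrays. The C/D small nucleolar RNA genes (104), which guide ribose methylation, had medians of −0.01 and 0.23 with 0 and 0 past 2-fold higher. Further guide RNAs past 2-fold in both lines were SNORA2B (1.68 in TE2 and 1.21 in TE15), SNORA67 (1.64 and 1.20), SCARNA8 (1.85 and 1.12) and SNORA38B (1.17 and 1.05). The primate-specific short SNAR RNA genes, 8 of them above background on at least 2 arrays, had medians of 0.25 and 1.30, with SNAR-F at 0.35 and 1.58. Collagens (18) had medians of −0.01 and −0.35, histone genes (71) of −0.01 and 0.12, and transfer RNA synthetases (17) of −0.06 and 0.21.

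Genes of the interferon pathway differed between the lines in both directions with siCont. RIGI and IFIH1, sensors of double-stranded RNA, were higher in TE15 than in TE2 by 3.01 and 2.40, and IRF7, an inducer of interferon genes, was above background on both TE15 arrays and on no TE2 array. The adaptor MAVS (−1.05), IRF3 (−0.99) and the double-stranded RNA-activated kinase EIF2AK2 (−0.63) were lower in TE15 than in TE2. With siCD63, IRF7 differed by 1.36 in TE15, RIGI by 1.32, IFIH1 by 1.43 and IRF9 by 1.52, while in TE2 RIGI differed by 0.26, IFIH1 by 0.27 and IRF9 by −0.34. The interferon gene IFNB1 was above background on the TE2 siCont array alone, at −5.37. The receptor genes IFNAR1, IFNAR2, IFNLR1 and IL10RB were above background on all 4 arrays.

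Interferon-stimulated genes were higher with siCD63 in TE15, with a median of 1.57 against 0.03 in TE2, or −0.06 over the 26 above background there. Signal of single probes is argued against for the listed genes with another probe, namely BST2, HERC6, IFIT2, OAS2, OAS3, PARP9, RIGI and XAF1. Their 9 other probes had a median of 1.39 in TE15 (bootstrap 95% interval 0.64 to 2.69), although those of RIGI and PARP9 gave 0.28 and 0.37. No such probe was available for IFI44L, RSAD2, IFI6, IFIT1, HERC5 or OASL. Leukocytes in the culture are argued against only weakly by a median of −0.34 over 11 leukocyte markers (−1.34 to 0.09). Some of these markers were bright in TE15 with siCont, such as CD14 (1.83) and CORO1A (−0.20). Their median therefore follows in part the RNA of the line itself. A response to the duplex cannot be told apart from loss of CD63, since 1 siRNA preparation was used against CD63. The difference between the lines stays open as an untested biological explanation.

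Besides CD63, 89 genes were at least 2-fold lower in both lines, among them GSDME (−2.35 and −2.12). Chance overlap is argued against by an expected count of 5.46 (Fisher's exact test across genes, p = 1.01e-86). Among the brightest 3344 genes, 11 were such genes against 0.134 expected (Fisher's exact test across genes, p = 6.36e-21). For those 11 genes only, this argues against the higher background of the siCD63 arrays. The dimmer genes of the set were not covered by that count. The median processed signal of the negative control spots was higher with siCD63 (6.30 against 5.29 in TE2, 6.02 against 5.24 in TE15). Background left in the signal raises dim values, so for the dimmer genes these medians argue against it as the cause of lower ones. With normexp background correction 39 genes, CD63 included, were at least 2-fold lower in both lines against 0.924 expected. The reported count with CD63 was 90, but the normexp offset by itself shrinks differences of dim genes, so the lower count is no measure of background. Other probes, 22 in number, had a median of −0.50 with an interval of −1.05 to −0.21. Of them 17 were lower in TE2 (median −0.60) and 17 in TE15 (median −0.60). They cover 19 of the 81 such genes above background on all arrays, and the upper end of the interval missed the limit set for this test. Signal of single probes therefore cannot be told apart from a lower transcript for the whole set. Partial matches of the duplex to other transcripts could lower the same genes in both lines and cannot be told apart from loss of CD63 with 1 siRNA preparation.

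The guide RNAs SCARNA13, SNORA51, SCARNA1 and SNORA48 were higher with siCD63 in both lines, with differences from 1.45 to 1.73. SCARNA1, dim with siCont (−6.08 in TE2 and −6.47 in TE15), had a mean difference of 0.81 with normexp background correction against 1.52 as reported. The normexp offset shrinks the differences of dim genes such as SCARNA1. Better recovery of all short nuclear RNA is argued against as the whole cause by a median of 0.17 (0.13 to 0.20) over 213 small nucleolar and Cajal body RNA genes; the 18S ribosomal RNA probe RNA18SN5 differed by 2.12 in TE2 and 0.27 in TE15, and a change in recovery of part of these RNAs stays open. A higher level of host gene RNA is argued against by a highest mean difference of 0.31, for NOP56, with −0.35 for SNHG10, −0.02 for PPP1R8 and 0.01 for EIF4A1. The probes measure RNA level, so they cannot decide whether transcription of the host genes was higher. Release of the guides from host introns, or a change in their turnover, may account for the values and was not tested.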
